A study of Mus musculus with 13 samples.

How the data were processed

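Liver endothelial cells of wild-type mice were profiled by RNA sequencing in 13 libraries, 7 from conventionally raised and 6 from germ-free animals. Per the labels' protocols, total RNA was checked for concentration and integrity, stranded poly(A) libraries were prepared with a commercial kit, and all were read on a single type of Illumina instrument. The authors deposited 1 table of raw counts per gene symbol with 1 column per library. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.5a, featureCounts 2.0.1 of Subread and DESeq2 1.42.1 were used with the mouse build mm10. The gene annotation, the strand setting, the treatment of reads that map to several places and any filter are not given in the sources used here. Genes with near-identical copies, such as the Mup and Cyp3a families, and antisense or overlapping genes can therefore share or lose reads. The table held 24421 symbols with 0 duplicates and 0 columns outside the series. Of these symbols 23204 matched the RefSeq annotation of GRCm38, the same build, from which coordinates were taken. Mitochondrially encoded genes are not among the symbols, so that list could not be tested.

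Groups came from the labels. The labels name no batch, sex, litter, age, day or cage, and do not say how the cells were isolated or whether each library is 1 animal, so p-values measure the spread between these libraries. Library names carry a letter-number code, whose number is 10 for CONV-R libraries 1 to 4, 9 for CONV-R 5 to 7 and 6 for all GF libraries. What this code stands for is not stated, and since no number occurs in both groups, it cannot be separated from the group. Within CONV-R, depth ranged from 18276439 to 32869515 counts at number 10 and from 7590320 to 15523860 at number 9. Counting error covers only part of the variation; the biological coefficient of variation was 0.264 across genes. No library pair of a group agreed within sampling noise (lowest chi-square per degree of freedom 13.4 over genes with at least 20 counts).

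The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and fitted with robust quasi-likelihood models of group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are GF over CONV-R, their standard errors are the absolute log2 fold change divided by the square root of the F statistic, and CPM refer to the TMM-scaled library. Gene lists, 40 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested, adjusted over 38 lists. Shares of marker genes are in CPM of the unscaled library total, compared on the log2 scale with a pseudocount of 1 by exact two-sided permutation tests over all 1716 splits, whose smallest possible p is 5.83e-04, adjusted over 12 lists of other cell types. Of the members of these lists, 2 were found under an older symbol.

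The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named genes are the 10 highest and 10 lowest log2 fold changes and the 5 smallest p in each direction, among genes past the threshold with a mean of at least 1 CPM and a symbol that is not a predicted gene, clone or receptor segment. In each list up to 4 members past the threshold were added, or the most abundant one where none passed, plus 12 fixed genes. The rule named 152 genes, 146 of them past the threshold, and 148 of these entered the alternatives and the search for single far libraries; the others are not reported here, which did not depend on their results. Which of them the text describes was chosen after their values had been seen.

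The alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2's size factors or library totals in place of TMM, no filter or a stricter filter on low counts, a threshold of 0.01, each CONV-R code number alone, the hepatocyte or Kupffer cell share as a covariate, and leaving out each library. Camera with an estimated correlation and fry were used for lists, and the mean log2 CPM of members for marker shares. Chosen after seeing the data were leaving out CONV-R 1 and 7 (highest hepatocyte shares), leaving out CONV-R 6 and 7 (highest immediate early and neutrophil levels), keeping CONV-R 2, 3 and 4 only, and removing each library's trend with transcript length and GC content, for which 96.4% of tested genes had a value.

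The fit was tested on simulated data for this comparison, with counts of 13847 genes drawn from the real means, library sizes and dispersions and 200 genes changed. It recovered 40.3% of 67 genes changed 1.5-fold, 71.6% of 67 changed 2-fold and 92.4% of 66 changed 4-fold, with 2.86% false calls, and called 0 genes when none had been changed. Genes were drawn independently, with the same dispersion in both groups. The real CONV-R libraries differed more from each other than the GF libraries (mean pairwise correlation 0.957 against 0.987), so these rates may not hold for the real counts.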

Results

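Bulk RNA sequencing was used to compare liver endothelial cells from wild-type mice raised conventionally, with a normal microbiota (CONV-R, n = 7), and from germ-free mice, which carry no live microbes (GF, n = 6). Liver endothelial cells line the sinusoids and the larger vessels of the liver, where they meet blood draining from the gut, and the comparison asks how their transcriptome differs when the microbiota is missing. The library totals ranged from 7590320 to 32869515 counts in CONV-R and from 23407168 to 35478115 in GF. The difference in depth was within the spread between libraries (exact two-sided permutation test, p = 0.0880). Counts were given for 24421 gene symbols, of which 18974 had a count in at least 1 library and 13915 were abundant enough to be tested.

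Genes higher in GF were led by Zbtb16, which encodes a zinc finger transcription factor and rose 45.5-fold, from 3.19 ± 1.70 to 144 ± 41.7 CPM (mean ± SD, log2 fold change 5.51 ± 0.33 SE, adjusted p = 6.78e-07). Map3k6, a stress-responsive MAP kinase kinase kinase, rose from 12.3 ± 3.01 to 113 ± 26.6 CPM (log2 fold change 3.21 ± 0.19, adjusted p = 6.78e-07). Fgfr1, a fibroblast growth factor receptor, rose 3.21-fold with the smallest p of all genes (log2 fold change 1.68 ± 0.08, adjusted p = 7.62e-08). Sgms1, a sphingomyelin synthase, rose 4.57-fold and Qsox1, a sulfhydryl oxidase, 2.77-fold. Among the 10 largest rises were also those of Syt4 (log2 fold change 3.74 ± 0.34), Fam107a (3.42 ± 0.41), the bile acid transporter family member Slc10a6 (3.05 ± 0.34), Lancl3 (2.83 ± 0.29), Sox11 (2.59 ± 0.47) and A2m (2.49 ± 0.22). In each of the genes named so far, except Sox11 with 5 of 6, all 6 GF libraries lay above every CONV-R library. The collagen genes Col1a1 (4.20 ± 1.40) and Col1a2 (3.21 ± 1.10) passed the threshold because of GF library 11, and without it their log2 fold changes were -0.67 and -0.23. Both calls were also lost on leaving out any CONV-R library, and that of Col1a2 without GF library 9.

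Genes lower in GF were led by Cyp3a11, a major drug-metabolising cytochrome P450 of hepatocytes, which fell from 199 ± 217 to 1.16 ± 0.25 CPM (log2 fold change -7.42 ± 0.92, adjusted p = 2.15e-04). Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, had a log2 fold change of -4.67 ± 0.87, and of -4.08 without CONV-R library 7 and -5.62 without GF library 12. Its counts were low, at 19 to 261 per CONV-R library and 1 to 28 per GF library. The fibrinogen-like gene Fgl1 (-4.26 ± 0.89) and the major urinary protein genes Mup14 (-4.59 ± 0.91) and Mup7 (-4.03 ± 0.87) fell as well. Mup genes are near-identical copies, so their counts are uncertain. For Fgl1, CONV-R libraries 2, 3 and 4 stood at 3.34, 1.73 and 1.28 CPM, against 1.15 to 1.73 in GF. The other CONV-R libraries held 33.4 to 60.5 CPM of Fgl1. Mup7 stood at 13.4 to 21.96 CPM in CONV-R 2, 3 and 4, against 3.76 to 15.7 in GF. Below every CONV-R library lay 2 of 6 GF libraries for Fgl1, 4 for Mup7 and 6 for Mup14. With the hepatocyte share as a covariate Mup7 stood at 0.18. Irg1, the gene of the itaconate-producing enzyme of activated macrophages, changed by -3.78 ± 0.74, or by -3.16 without CONV-R library 6. The immune-cell genes Siglech (-4.29 ± 1.12), Il5ra (-3.88 ± 0.99) and Pax5 (-3.78 ± 0.95) and the calcium channel gene Cacna1i (-3.76 ± 0.99) were very high in CONV-R library 1. Without that library their log2 fold changes were -1.82, -2.08, -1.82 and -1.64, all still past the threshold. Of genes with small spread, Csf1, the macrophage colony-stimulating factor gene, fell from 261 ± 47.2 to 94.3 ± 1.63 CPM (log2 fold change -1.47 ± 0.11, adjusted p = 3.57e-06). Adam19, a membrane metalloprotease gene, fell 2.21-fold, Sh2b2 2.09-fold and Tmem97 1.82-fold, each with all 6 GF libraries below every CONV-R library.

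**Figure D1:**
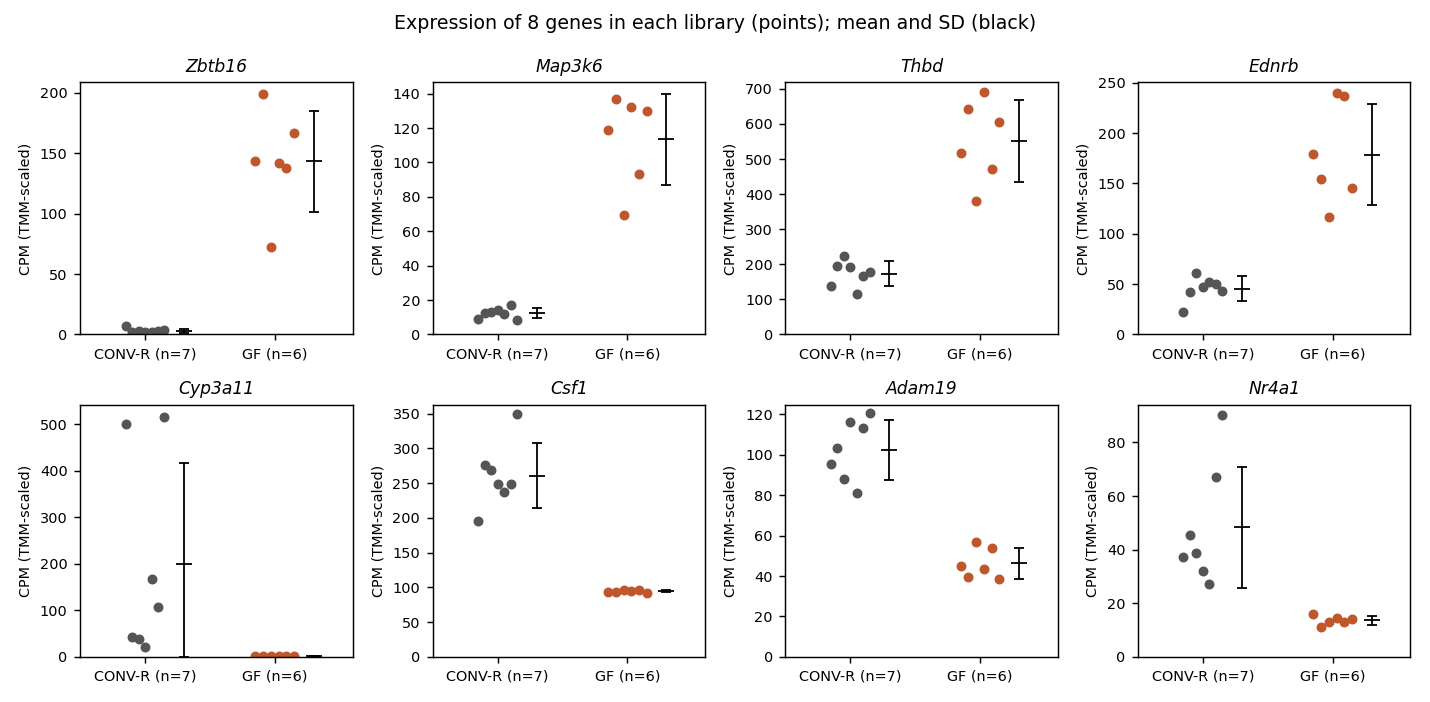
Each point is 1 library, the horizontal axis separates CONV-R (n = 7) from GF (n = 6), and the vertical axis is CPM after TMM scaling, from 0; black marks give the mean and SD, with the lower bar stopped at 0. Zbtb16, Map3k6, Thbd and Ednrb lay higher in all 6 GF libraries, while Cyp3a11, Csf1, Adam19 and Nr4a1 lay lower, with Csf1 at 94.3 ± 1.63 CPM in GF.

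In the mouse genome build GRCm38 (the RefSeq annotation of the build the submitters call mm10), these genes lie as follows. Zbtb16 spans chromosome 9 from 48651797 to 48836225, and Adam19 chromosome 11 from 46054502 to 46147347. Map3k6 spans chromosome 4 from 133237979 to 133252929, Fgfr1 chromosome 8 from 25518759 to 25575718, and Thbd chromosome 2 from 148404471 to 148408188. Cyp3a11 spans chromosome 5 from 145854607 to 145879854, and Csf1 chromosome 3 from 107741048 to 107760469. All of these are annotated as protein-coding genes, and counts are summed per gene.

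Over all tested genes, 1593 were higher and 1764 lower in GF (24.1% of 13915 together; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 1043 differed at least 2-fold, 234 of them higher and 809 lower. All 6 GF libraries lay above every CONV-R library for 804 of the higher genes, and below for 591 of the lower genes. Against the 4 CONV-R libraries with code number 10 alone 978 genes were higher and 1000 lower, and against the 3 with code number 9 alone 2281 were higher and 2526 lower. With library totals in place of TMM scaling, the split was 971 higher against 2773 lower (25.9% higher, against 47.5%), with the median log2 fold change of all genes at -0.11 in place of -0.01. With each library's hepatocyte marker share as a covariate, 283 genes were higher, 265 lower and 211 changed at least 2-fold; without GF library 9, 1013 were higher. The GF libraries resembled each other more closely (mean pairwise correlation of log2 CPM 0.987) than the CONV-R libraries did (0.957). The first principal component held 45.2% of the variance and ran from -84.1 to 4.41 in CONV-R and from 27.9 to 40.8 in GF.

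Markers of other liver cells were lower in GF for hepatocytes and several leukocytes, and higher for cholangiocytes. The summed hepatocyte markers fell from 6963 ± 4952 to 1606 ± 268 CPM of the library total, the unit of all shares here (exact permutation test, adjusted p = 0.00874), and 25 of 27 tested members fell (26 adjusted over the list alone), among them Hp (log2 fold change -3.52 ± 0.63), Fgg (-3.02 ± 0.52) and Alb (-1.70 ± 0.35). The neutrophil and monocyte share fell from 1050 ± 868 to 252 ± 108 (adjusted p = 0.00979, exact permutation test), with 13 of 17 members lower (14 adjusted over the list alone), such as Retnlg (-2.98 ± 0.54) and the receptor gene Csf3r (-2.55 ± 0.54; -1.95 without CONV-R library 7). The B and plasma cell share fell from 395 ± 785 to 38.7 ± 8.06 (adjusted p = 0.00466, exact permutation test), and 11 of 12 members fell (11 adjusted over the list alone). CONV-R library 1 held 2175 of it, and without that library the log2 difference went from -1.98 to -1.34. Without it the list's median was also -1.21 rather than -3.25. The dendritic cell share was 695 ± 113 in CONV-R and 599 ± 32.4 in GF (adjusted p = 0.0360, exact permutation test), and 7 of its 14 members fell (9 adjusted over the list alone). That call was lost on leaving out any 1 of CONV-R 1, 6 or 7 or of the GF libraries, with adjusted p from 0.0519 to 0.116, and without CONV-R 1 the log2 difference went from -0.20 to -0.13. The camera gene-set test also placed these 4 lists lower, with adjusted p from 3.28e-16 to 0.0277, but with an estimated correlation the adjusted p = 0.301 for hepatocytes, 0.301 for neutrophils and monocytes, 0.614 for B cells and 0.614 for dendritic cells. Without GF library 10 the dendritic list's camera adjusted p was 0.0504, with library totals in place of TMM 0.108, and without CONV-R library 1 its median went from -1.09 to -0.66.

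The cholangiocyte share, from genes of the bile duct epithelium, rose from 180 ± 107.3 to 378 ± 112 (adjusted p = 0.0198, exact permutation test), and 7 of 11 members rose (8 adjusted over the list alone), including the keratin gene Krt7 (1.26 ± 0.30) and Epcam (1.22 ± 0.32). The list's camera call (adjusted p = 1.26e-05) was lost at adjusted p = 0.301 with an estimated correlation. The lymphatic endothelium share rose from 2132 ± 467 to 3016 ± 211 (adjusted p = 0.00466, exact permutation test), a list that holds Flt4 and Lyve1, which are also in the sinusoidal identity list. After TMM scaling Flt4 stood at 902 to 2082 CPM in CONV-R and 1990 to 2586 in GF. Prox1 stood at only 2.19 to 4.28 and 3.77 to 6.27, so the share does not measure lymphatic cells alone. In the lymphatic list 4 of 7 members rose (4 adjusted over the list alone), with camera adjusted p = 0.0277, p = 0.0540 without CONV-R library 4, and adjusted p = 0.245 with an estimated correlation. The platelet share rose from 109 ± 23.9 to 290 ± 55.9 (adjusted p = 0.00466, exact permutation test), but Itgb3, an integrin gene that endothelial cells also express, was the only 1 of 9 members past the threshold (1 adjusted over the list alone; 2.03 ± 0.21). With the mean log2 CPM of the members in place of their sum, the platelet difference was 0.24 and did not pass (adjusted p = 0.233). The Kupffer cell share (7089 ± 2881 against 4622 ± 657, adjusted p = 0.112, exact permutation test) did not pass, except without CONV-R library 4 (adjusted p = 0.0433). None of its 16 members passed (0 adjusted over the list alone), with Clec4f at -0.66 ± 0.27, although camera placed the list lower (adjusted p = 0.00455; adjusted p = 0.687 with an estimated correlation). Clec4f itself passed without CONV-R library 3 (-0.76) or 4 (-0.77). Shares of T and NK cells (adjusted p = 0.642), stellate cells and fibroblasts (adjusted p = 0.371), erythroid cells (adjusted p = 0.204) and continuous endothelium (adjusted p = 0.0516) did not pass the exact permutation test. The continuous endothelium share did pass without CONV-R 2, 3 or 4 or GF 10, with adjusted p from 0.0292 to 0.0411, and with the mean log2 CPM of members (difference 0.38, adjusted p = 0.0140).

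**Figure D2:**
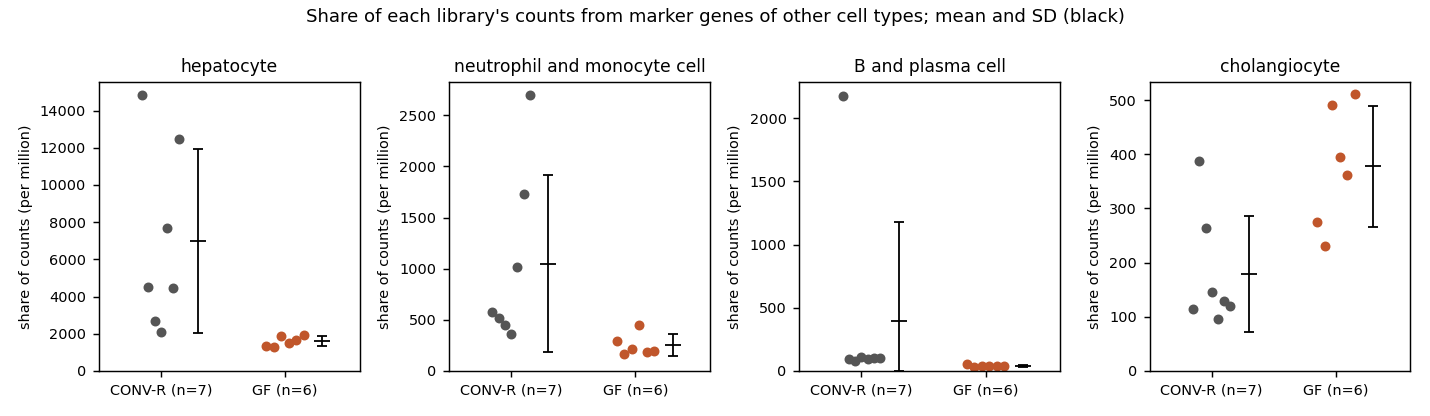
Points are libraries of CONV-R (n = 7) and GF (n = 6), and the vertical axis is the share of a library's counts that falls on a fixed list of marker genes, in CPM of the library total; black marks give the mean and SD, with the lower bar stopped at 0. Hepatocyte, neutrophil and monocyte, and B cell shares were lower in GF and the cholangiocyte share higher, and CONV-R library 1 stood at 2175 in the B cell panel.

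Cholesterol biosynthesis genes fell together in GF, with 20 of 25 tested members lower and 0 higher (22 lower adjusted over the list alone). Members with small p were Msmo1 (log2 fold change -0.85 ± 0.11), Hsd17b7 (-0.94 ± 0.12) and the lanosterol demethylase gene Cyp51 (-1.47 ± 0.20), all enzymes of the later steps. The list's median was -0.70 (camera adjusted p = 4.50e-14; adjusted p = 0.245 with an estimated correlation). Hepatocyte markers, whose cells express this pathway, fell in the same libraries, from 6963 to 1606 CPM. The median was -0.94 against code number 10 alone and -0.50 against code number 9 alone. With the hepatocyte share as a covariate 7 members were lower and the median was -0.49.

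**Figure D3:**
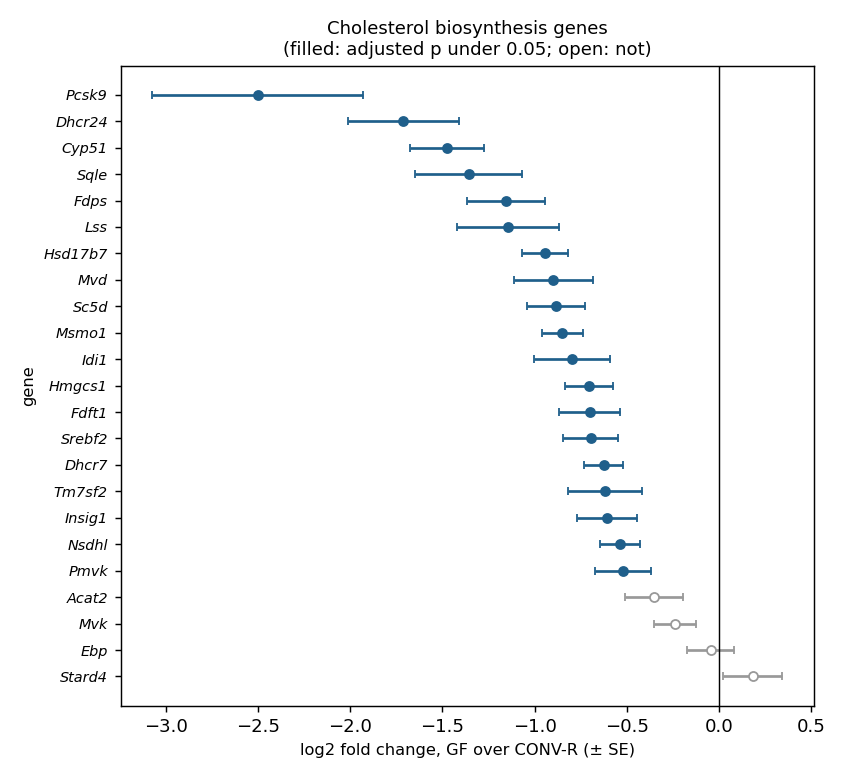
Log2 fold changes of 23 members of the cholesterol list, GF over CONV-R, on the horizontal axis, with 1 gene per line; bars are standard errors and filled points passed the adjusted p threshold. The points of 19 of these genes are filled and lie left of 0, and 4 are open.

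Lipid handling genes moved in both directions, with 6 of 20 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.109, and 0.0337 without CONV-R library 5). Cd36, a fatty acid transporter gene, rose from 880 ± 190 to 1644 ± 132 CPM (log2 fold change 0.90 ± 0.14), and Fabp5 changed by 0.91 ± 0.10. Gpihbp1, which anchors lipoprotein lipase to capillaries, changed by 0.59 ± 0.13, whereas Lpl itself changed by -0.84 ± 0.21. Lpl stood at 219 and 296 CPM in CONV-R 5 and 6, which had the highest Kupffer cell shares (10531 and 10249). The other CONV-R libraries held 108 to 157 CPM of Lpl, overlapping 77.3 to 117 in GF. CONV-R 1, with a Kupffer cell share of 9325, held 140. In the sphingolipid list 7 of 31 genes were higher, 1 was lower and 23 passed in neither direction (9 higher and 2 lower adjusted over the list alone), with a median of 0.08. The higher genes included the ceramidase gene Acer2 (1.09 ± 0.12) and the sphingosine phosphate receptor gene S1pr1 (1.06 ± 0.11), next to Sgms1. The camera call (adjusted p = 0.00148) was lost at adjusted p = 0.245 with an estimated correlation.

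Genes of sinusoidal endothelial identity were higher in GF for 6 of 24 members and lower for 2 (7 and 2 adjusted over the list alone). Lyve1, the hyaluronan receptor gene, rose 1.91-fold (log2 fold change 0.93 ± 0.13), Oit3 1.58-fold and Gpr182 1.37-fold, and Tfec fell (-0.48 ± 0.08). Stab2, a scavenger receptor gene, changed by 0.39 ± 0.13 (adjusted p = 0.0468), a call that was lost on leaving out any library but CONV-R 1 or 4, with adjusted p from 0.0564 to 0.0985, and with library totals in place of TMM (0.0852). F8, coagulation factor VIII, stood at 0.15 ± 0.11 (adjusted p = 0.330). Camera placed the list higher (adjusted p = 0.00148; adjusted p = 0.614 with an estimated correlation). In the scavenging and lysosome list, 3 of 22 were higher and 2 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.874). The share of counts on identity genes was 48509 ± 7089 CPM in CONV-R and 55576 ± 1692 in GF, alongside the lower hepatocyte and leukocyte shares.

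The lists of both endothelial zones held more higher than lower genes. Of 10 pericentral genes 5 rose and 1 fell (6 and 1 adjusted over the list alone): Wnt2, the central vein Wnt ligand gene, changed by 0.88 ± 0.17, Cdh13 by 0.76 ± 0.13, Thbd by 1.67 ± 0.16 and Gatm by -0.53 ± 0.12. Of 14 genes in the periportal list 5 rose and 1 fell (5 and 1 adjusted over the list alone), among them Efnb2 (0.67 ± 0.14) and Ltbp4 (0.56 ± 0.11). The list also counts the glutamine synthetase gene Glul (1.29 ± 0.12) as periportal, a placement that was not tested here. Both camera calls (adjusted p = 5.40e-04 and 3.10e-04) were lost with an estimated correlation (adjusted p = 0.358 and 0.301). In the continuous endothelium list 4 of 21 rose (4 adjusted over the list alone; camera adjusted p = 0.00148, adjusted p = 0.404 with an estimated correlation), and Vwf stood at 0.55 ± 0.20 (adjusted p = 0.0619), or 0.73 and past the threshold without CONV-R library 3.

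Haemostasis genes rose in 8 of 23 members and fell in 1 (9 and 1 adjusted over the list alone). Thbd, the anticoagulant thrombomodulin, rose from 173 ± 36.5 to 551 ± 116.3 CPM (adjusted p = 3.50e-05), Plat changed by 0.87 ± 0.20, the thrombin receptor gene F2r by 0.66 ± 0.16 and the protein S gene Pros1 by 0.42 ± 0.10. The list's median was 0.35, and 0.23 without GF library 11. Vascular tone genes rose in 7 of 21 members and fell in 2 (7 and 3 adjusted over the list alone). Ednrb, the endothelin B receptor gene, rose from 45.5 ± 12.1 to 179 ± 50.4 CPM, Nos3, the endothelial nitric oxide synthase gene, changed by 0.70 ± 0.09 and Ramp2 by 0.78 ± 0.10, and the prostaglandin synthase gene Ptgs2 by -2.50 ± 0.57, or -1.86 without CONV-R library 7. The camera calls (adjusted p = 5.18e-04 for haemostasis and 0.00249 for tone) were lost with an estimated correlation (adjusted p = 0.245 and 0.358).

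Signalling lists of the endothelium held more higher than lower genes. Notch genes rose in 5 of 16 members and fell in 1 (5 and 2 adjusted over the list alone), with Lfng at 1.16 ± 0.14, Notch4 at 0.85 ± 0.15 and Dll1 at 0.42 ± 0.06; the list's median was 0.19, and 0.09 without GF library 9. TGF-beta and BMP genes rose in 9 of 24 and fell in 1 (10 and 1 adjusted over the list alone). Bmper, a secreted BMP regulator, rose 4.91-fold (2.30 ± 0.24), Bmpr2 1.58-fold and Smad7 1.33-fold. VEGF and angiopoietin genes rose in 9 of 20 and fell in 2 (9 and 2 adjusted over the list alone), including the receptor genes Flt1 (0.39 ± 0.10) and Tek (0.37 ± 0.10), while Vegfb (-0.39 ± 0.06) and the tight junction gene Cldn5 (-0.54 ± 0.13) were lower. Camera adjusted p values were 0.0112, 0.00119 and 0.0273, and with an estimated correlation the adjusted p = 0.301, 0.404 and 0.685 in this order; without CONV-R library 1 the VEGF call was lost (adjusted p = 0.0588). With the hepatocyte share as a covariate the camera calls of the identity, zonation, continuous endothelium, haemostasis, tone, Notch, TGF-beta, VEGF, lymphatic and sphingolipid lists ended, with adjusted p from 0.0950 to 0.862.

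NF-kB targets and immediate early genes held more lower than higher members in GF. Of 23 tested NF-kB targets 10 fell and 1 rose (14 and 1 adjusted over the list alone), led by Relb (log2 fold change -0.88 ± 0.09), Tnf (-1.86 ± 0.24), Tnfaip2 (-1.38 ± 0.21) and Nfkbie (-0.75 ± 0.12); camera gave adjusted p = 1.26e-05 and an adjusted p = 0.114 with an estimated correlation. Immediate early genes, which tissue handling can induce, fell in 12 of 21 members with 0 higher (16 lower adjusted over the list alone), among them Nr4a1 (-1.82 ± 0.25), Atf3 (-1.25 ± 0.21), Zfp36 (-1.37 ± 0.25) and Myc (-1.39 ± 0.27). Their share was 2288 CPM in CONV-R 6 and 2694 in CONV-R 7, against 1089 to 1277 in the other CONV-R libraries and 791 to 1006 in GF. Without these 2 libraries 11 members were lower and 1 higher, and the list's median was -0.58 rather than -1.15. No member passed with the hepatocyte share as a covariate, where the median was -0.64, though camera at its preset correlation still called the list. The camera call (adjusted p = 4.33e-07) was lost at adjusted p = 0.301 with an estimated correlation. The neutrophil and monocyte share fell in the same libraries, from 1050 to 252 CPM. In the MHC class II list 4 of 11 fell (4 adjusted over the list alone), with H2-DMb2 at -3.31 ± 0.87, or -1.50 without CONV-R library 1, which was the library with the most B cell markers. Without it the list's median went from -0.80 to -0.34; camera gave adjusted p = 0.0295, 0.0743 without GF library 10, 0.131 with library totals, and an adjusted p = 0.723 with an estimated correlation.

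Pattern recognition genes rose in 2 of 25 members and fell in 5 (2 and 5 adjusted over the list alone; camera adjusted p = 0.375). Tlr2 changed by -0.41 ± 0.09, Tlr1 by -2.01 ± 0.49 (-1.34 without CONV-R library 1) and the lipopolysaccharide-binding protein gene Lbp by 0.67 ± 0.10, whereas Tlr4, the lipopolysaccharide receptor gene, stood at 0.19 ± 0.08 (adjusted p = 0.0969). Type I interferon genes were split, with 3 of 30 higher and 3 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.971), including Cmpk2 (0.38 ± 0.08) and Mx1 (-1.23 ± 0.29), which the reference genome annotates as a transcribed pseudogene. Against the 3 CONV-R libraries with code number 9 alone that list was lower in GF, with 15 members down, and against the 4 with code number 10 it was higher, with 8 up. Interferon gamma genes were higher in 1 of 20 and lower in 4 (2 and 4 adjusted over the list alone; camera adjusted p = 0.8292), with the checkpoint ligand gene Cd274 at -0.97 ± 0.14. MHC class I genes were higher in 1 of 16 and lower in 0 (1 and 0 adjusted over the list alone; camera adjusted p = 0.971). The type I list had a median of -0.01, a mean of -0.15 and an upward camera direction, and the interferon gamma list a median of 0.01, a mean of -0.12 and a downward one.

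Clock genes were higher in 7 of 20 members and lower in 0 (8 and 2 adjusted over the list alone), with Per1 at 1.26 ± 0.21, Nr1d1 at 1.16 ± 0.30, Dbp at 0.88 ± 0.19 and Nr1d2 at 0.81 ± 0.14; the time of day of collection is not given in the sources used here. Camera gave adjusted p = 0.0170, and an adjusted p = 0.358 with an estimated correlation. Xdh, xanthine dehydrogenase, rose from 463 ± 93.4 to 1253 ± 101.3 CPM within an oxidative stress list that had 2 of 27 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.412). Of 8 aryl hydrocarbon receptor targets 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.885): Cyp1a1 changed by 1.81 ± 0.34 and Cyp1a2, which hepatocytes express strongly, by -2.52 ± 0.57. The unfolded protein response list had 3 of 21 higher and 6 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.208), and the heat shock list 2 of 14 higher (2 adjusted over the list alone; camera adjusted p = 0.885). Cell cycle genes were higher in 1 of 24 (0 adjusted over the list alone; camera adjusted p = 0.0517). The cell cycle list passed as higher in 9 of 11 other settings (adjusted p from 4.98e-06 to 0.0492) and on leaving out CONV-R 5, 6 or 7 or GF 9, 10, 12 or 13 (0.00435 to 0.0394), but not with the stricter filter (0.0510), against code number 9 alone (0.848) or with an estimated correlation (0.755). Of the remaining marker lists, T and NK cell genes fell in 1 of 17 members, Cd8b1 (0 adjusted over the list alone; camera adjusted p = 0.580). Without CONV-R library 1 Cd8b1 went from -3.08 to -0.85 and did not pass (adjusted p = 0.0579), and the T and NK cell share difference went from -0.16 to 0.13; the Cd8b1 call was also lost without any 1 GF library (adjusted p from 0.0516 to 0.0774). Stellate cell genes rose in 2 of 18, the collagen genes above (0 adjusted over the list alone; camera adjusted p = 0.348). Of 3 erythroid genes Car2 rose and Alas2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.655). The platelet list had camera adjusted p = 0.372. Nuclear oxidative phosphorylation genes were higher in 1 of 34 (0 adjusted over the list alone; camera adjusted p = 0.243, and 0.0464 without CONV-R library 5).

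Of the 38 gene lists tested, camera with its preset correlation called 22, of which 13 were higher and 9 lower in GF. With an estimated correlation it called 0, while fry, which tests whether a list's genes move one way on balance, called 16. In the 11 other settings of the gene fit, camera did not call VEGF and lymphatic lists in 5, Kupffer cells in 4, MHC class II in 3, and dendritic cells, continuous endothelium, pericentral endothelium, Notch and vascular tone in 2. Only with the hepatocyte share as a covariate did it not call hepatocytes (adjusted p = 0.843), neutrophils and monocytes (0.0950), B and plasma cells (0.576), sinusoidal identity, periportal endothelium, haemostasis, TGF-beta and sphingolipids. For hepatocytes that loss was fixed in advance, since the covariate is computed from the same genes. The cholesterol, NF-kB, immediate early, clock and cholangiocyte lists were called in all 11, each at the preset correlation. Lists were not tested with the Kupffer cell share as a covariate, which is not among the 11. Camera also called some lists that had not passed: type I interferon in 5, heat shock in 3, lipid handling in 2, and pattern recognition, the unfolded protein response and oxidative phosphorylation in 1. Other splits of the 13 libraries gave a median of 17 camera calls, and 12 of 100 splits, the real one included, gave at least 22, so chance is not excluded for that count. The median, the mean and the camera direction also differed in sign for the heat shock (0.01, -0.28, upward), aryl hydrocarbon receptor (-0.08, -0.13, upward) and scavenging (-0.03, -0.02, upward) lists. Y-linked Ddx3y was detected in every library (133 ± 22.3 CPM in CONV-R, 122 ± 30.5 in GF), and 0 of 4 sex-linked genes tested passed the threshold (0 adjusted over the list alone).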

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

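The tests of Cyp3a11, of the germ-free state and of the cholesterol list mean per library were chosen after the result was seen, as was the alternative that removes length and GC trends.

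Of 324 groups of values examined for a single far library (library totals, marker shares and 148 named genes in each group), 45 had one. Chance gives about 5% for unselected and independent values. Most of these genes were named by their results in the same libraries, and many vary together, so that rate does not apply directly. CONV-R library 1 accounted for 31. It had the highest shares of B and plasma cell markers (2175 CPM of the library total, other CONV-R libraries 80.5 to 110.1), T and NK cell markers (538) and dendritic cell markers (935), and the lowest share of sinusoidal endothelial identity genes (34156, others 46078 to 55212). It was highest in the leukocyte genes Fcer2a (206 CPM), Blk (95.4), Pax5 (37.0), Siglech (75.5), Ccr7 (67.5), Flt3 (15.9), Cd209a (11.4), Cd8b1 (19.5) and Il5ra (12.4). It was also highest in the antigen presentation genes H2-Ob (272), H2-DMb2 (117), Ciita (115) and H2-Oa (39.1), and in Cacna1i (55.7) and Dnajb1 (43.4). It was lowest in the endothelial genes Stab2 (2701 CPM), Mrc1 (2161), F8 (1099), Flt1 (518), Pros1 (411), Nid1 (385), Bmpr2 (263), Nos3 (131), Notch4 (100.98) and Ednrb (21.8), and in Rsad2 (70.9) and Col1a2 (1.06).

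GF library 11 was highest in Col1a1 (154 CPM, other GF libraries 0.4928 to 1.19), Col1a2 (146) and the stellate cell and fibroblast share (2569 CPM of the library total), and lowest in the dendritic cell share (539). GF library 10 was lowest in Zbtb16 (72.3 CPM, others 138 to 199), Slc10a6 (14.5) and Ddx3y (63.3). GF library 12 was lowest in Lfng (115 CPM) and Wnt2 (244). GF library 8 was highest in the T and NK cell share (329 CPM of the library total), H2-DMb2 (3.51 CPM) and H2-Ob (7.85 CPM). CONV-R library 5 was lowest in Hsd17b7 (6.06 CPM) and CONV-R library 3 in Socs1 (4.06 CPM).

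In 100 of the 1716 possible splits of the 13 libraries into 7 and 6, the real one included, 1 split reached 1593 higher genes, 1 reached 1764 lower genes and 1 reached 1043 genes changed at least 2-fold, which was the real split each time. The highest other values were 3, 0 and 3 genes, so no other drawn split gave as many. Every other split mixes the groups, which moves the group difference into the spread within groups and leaves few calls. The other split with the most calls held 5 of the GF libraries together and still called only 3 genes. With this limit and 100 splits drawn, the test cannot exclude chance assignment of libraries. For the 22 gene lists called by camera, 12 of the 100 splits gave as many and the highest other gave 26, so chance is not excluded for that count.

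Cyp3a11 fell further than the hepatocyte markers around it. Relative to the other hepatocyte markers it was 28.9-fold lower in GF (log2 ratio -4.86, exact permutation p = 5.83e-04, the smallest these splits can give), at 2.37 ± 1.37% of their counts in CONV-R (n = 7) and 0.0702 ± 0.0115% in GF (n = 6), which argues against a lower hepatocyte share as the whole cause. Reads passing to related genes might lower it: 1 of 2 other Cyp3a genes above 1 CPM, Cyp3a13, had a log2 fold change above 0 (0.07 ± 0.42), so a first criterion of any value above 0 was met, but by less than the error. The summed CPM of the 8 other Cyp3a genes was lower in GF by a difference of -25.8 CPM (36.6 ± 29.1 against 10.8 ± 2.24). With 10.8 CPM in GF, they did not take up most of the 198 CPM lost by Cyp3a11. Hepatocyte markers fell from 6963 to 1606 CPM in the same libraries, which lowers both values. This sum was not scaled to them, so a smaller transfer is not excluded. A response of hepatocytes to the germ-free state and an unstated difference between the library codes stay open and cannot be told apart.

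The fall of cholesterol biosynthesis genes was weighed against hepatocyte RNA in the CONV-R libraries. With the hepatocyte share as a covariate the median log2 fold change was -0.49 with a standard error of 0.13, against -0.70, short of the set bound in either direction. The bounds were set before this value was seen, but were based on the uncorrected median. It was also known by then that the list kept its direction with this covariate. The list's mean log2 CPM per library differed by -0.52 with a standard error of 0.186 in that fit, against -0.79 without the covariate, which decides neither way. The median was -0.84 against CONV-R 2, 3 and 4 only, a setting chosen after the result was seen, with 20 of 25 members lower. CONV-R 3 and 4 had the lowest hepatocyte shares of CONV-R, 2691 and 2084 CPM, against 1270 to 1943 in GF. Their list means were 4.13 and 4.31 log2 CPM, against 3.40 to 3.66 in GF. These values argue against hepatocyte RNA as the whole cause. After removing length and GC trends the median was -0.72, where the standard error of the uncorrected median over members was 0.151, which argues against such a trend. Mean expression of the list lay below every CONV-R library in 6 GF libraries, which is what a germ-free effect predicts, but the germ-free state and the library code cannot be told apart here. A part played by hepatocyte RNA stays open.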

How the results depend on the processing

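The alternatives that leave out CONV-R 1 and 7 or 6 and 7, keep CONV-R 2 to 4, or remove length and GC trends were chosen after the result was seen. The counts of genes higher, lower and changed at least 2-fold in GF were 629, 579 and 439 at an adjusted p under 0.01, which is stricter by construction, 978, 1000 and 608 against code number 10 only, 721, 608 and 305 with the Kupffer cell share as a covariate, and 283, 265 and 211 with the hepatocyte share. Of the genes called with the hepatocyte share, 337 were called without it, 330 in the same direction; the share itself differs between the groups, so this covariate takes up part of the group difference. Library totals gave 971 higher and 2773 lower. Genes changed at least 2-fold numbered 684 with limma-voom, 650 without CONV-R 1 and 7, and 472 against CONV-R 2, 3 and 4 only. Lists called numbered 0 with an estimated correlation and 8 with the hepatocyte share, and marker shares 4 against CONV-R 2, 3 and 4 only. With the mean log2 CPM of members 7 shares passed, but platelets were lost and continuous endothelium was gained. Other causes were not tested. Leaving out each library gave 1013 to 1765 higher, 1208 to 1972 lower, 792 to 1212 changed at least 2-fold, 21 to 25 lists and 6 to 9 marker shares. With the hepatocyte share the direction turned for Cyp1a2 (0.24), Mup7 (0.18), Gbp8 (0.18), Ciita (0.16), Cd8b1 (0.61), Ccr7 (0.22), Cav2 (-0.0048) and Mrc1 (-0.0084). It also turned for the medians of MHC class II (0.37), sinusoidal identity (-0.0509), continuous endothelium (-0.0176), VEGF and angiopoietin (-0.0609), TGF-beta and BMP (-0.00184), hepatocyte (0.0244) and Kupffer cell genes (0.18). None of these passed the threshold. The loss of the hepatocyte difference is built into this fit, since the covariate is computed from the same genes. For the others the cause was not tested. The Kupffer list turned against CONV-R 2, 3 and 4 only (0.17), the type I interferon list against code number 9 only (-0.22), and Col1a1 and Col1a2 without GF library 11, with -0.67 to 4.45 and -0.23 to 3.45 over the libraries left out. Of the comparisons of the 148 named genes under the other alternatives, 1822 kept the side of the threshold, 381 lost the call, 6 gained it and 8 turned. Among the 1822, 4 changed sign with neither fit past the threshold: Clec4f with the hepatocyte share (0.19), the Kupffer cell share (0.0464) and CONV-R 2, 3 and 4 only (0.16), and F8 with the hepatocyte share (-0.0299). Clec4f is itself counted in the Kupffer cell share, so that fit says little about it. Comparisons of lists and shares were counted in the same way. A change of sign with neither fit past the threshold was found in 35 of 409 list comparisons and 3 of 39 of marker shares. When leaving out 1 library, 1761 kept direction and side, 158 lost the call, 3 gained it and 2 turned, and 22 of 481 list comparisons and 1 of 142 of shares changed sign with neither fit past the threshold; the losses included those of Gbp8, Mrc1, Cav2, Prox1 and Flt4. Depth limits low genes most in CONV-R library 6, at 7590320 counts.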

Other observations

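The test of the hepatocyte share on the first list of glucocorticoid genes and that of the second list were set before their results were seen, while the test by the list mean per library was chosen after; the first list itself was put together after some of its genes had been seen among the largest changes, and its genes outside the rule for named genes were chosen after their values were seen.

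Several genes that glucocorticoids are known to induce were higher in GF. Fkbp5, a glucocorticoid receptor co-chaperone, rose from 85.7 ± 17.9 to 314 ± 72.1 CPM (log2 fold change 1.87 ± 0.17, adjusted p = 2.52e-05), Ddit4 from 37.3 ± 10.7 to 154 ± 42.9 and Klf9 from 76.6 ± 22.5 to 212 ± 36.6. Tsc22d3, an anti-inflammatory target, changed by 0.80 ± 0.14, Pdk4 by 0.90 ± 0.13 and Cdkn1a by 0.99 ± 0.15. Other classical targets did not pass the threshold: Sgk1 stood at 0.01 ± 0.14, Dusp1 at 0.15 ± 0.20, Mt1 at 0.36 ± 0.25 and Mt2 at 0.45 ± 0.30. In the first list 10 of 17 members were higher and 0 lower, with a median of 0.90. These 10 include Zbtb16, Map3k6 and Per1, already given above, and Hif3a, which was near the floor (0.23 CPM in CONV-R, 0.99 in GF). Since the list was put together after such changes had been seen, its count is not independent evidence.

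A candidate explanation is higher glucocorticoid receptor activity in GF. A second list of 17 such genes, not looked at before, had 4 of 16 tested members higher and 3 lower and a median of 0.0584. Camera's unadjusted p for this list was 0.379. Arrdc3 (0.75 ± 0.12), Klf15 (1.08 ± 0.17), Foxo3 and Lpin1 rose, while Anxa1 (-1.22 ± 0.19), Rgs2 and Irs2 fell, so members went both ways and the second list gave no evidence for the hypothesis. With the hepatocyte share as a covariate the first list's median was 1.01 with a standard error of 0.47 and 8 members were higher, which did not meet the bound set in advance, since the members differ widely. In the fit of the list's mean log2 CPM per library the difference was 1.20 with a standard error of 0.205, against 1.30 without the covariate, which argues against the hepatocyte share as the whole cause. Cells of other types were not tested. Time of collection and fasting also stay open, since neither is in the labels.

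Some clock genes set a pair of CONV-R libraries apart. Per2 was at 24.8 CPM in CONV-R 1 and 33.1 in CONV-R 7, against 4.57 to 7.11 in the other 5 CONV-R libraries and 29.5 to 39.0 in GF. Cry1 was at 22.1 and 26.0, against 5.86 to 8.10 and 6.70 to 8.52 in GF. Nr1d1 was at 58.2 and 59.7, against 80.2 to 226 and 247 to 321 in GF. Per3, Tef and Arntl also lay outside the range of the other CONV-R libraries in both, but Per1 (30.3 and 41.8, against 19.7 to 43.1) and, in CONV-R 7, Dbp (22.1, against 14.985 to 25.2) did not. The same pair had the highest hepatocyte shares, 14842 and 12454 CPM of the library total.

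In a comparison chosen after seeing Cyp3a11, 34 genes were taken relative to the other hepatocyte markers with the exact permutation test, and 22 passed, 14 lower and 8 higher in GF. Cyp7a1 was 7.004-fold lower in GF (adjusted p = 0.0116) and Cyp8b1, another bile acid synthesis gene, 2.39-fold lower (adjusted p = 0.0066). The Cyp7a1 value rests on few reads, 1 to 28 counts per GF library, and GF 12 with 28 lay above CONV-R 2 with 19. The fatty acid-binding protein gene Fabp1 was 2.46-fold higher (adjusted p = 0.0066), Hp 2.27-fold lower (adjusted p = 0.0225), and Alb 1.20-fold higher without passing (adjusted p = 0.367).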
